A study of Mus musculus with 12 samples.

How the data were processed

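RNA of CD11c cells from the inguinal lymph node was measured in 12 libraries, 4 from healthy mice, 4 from nodes draining a subcutaneous KPC tumor and 4 from such nodes of mice given a CD40 agonist. Per the labels' protocols, RNA was isolated with the Qiagen RNeasy Plus Micro kit and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand of the RNA. The dose and timing of the agonist, any control treatment of the other tumor-bearing mice, the purity of the cells and the sequencing run are not given in the sources used here. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

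The deposited estimated counts were made by the authors per transcript with Salmon on mouse build mm10, per the submitters' processing notes, and were not normalized. The deposited TPM values, transcript abundances scaled by the authors to the same total in each library, came from the same quantification, per the submitters' processing notes. The name under which both tables were deposited says sailfish, a related program. The program version, the annotation release and any filter are not given in the sources used here. Salmon divides reads that match several transcripts by a model, so that counts of near-identical genes, such as members of the Cd209, Gbp, Oas, Bcl2a1, histocompatibility and immunoglobulin families, are uncertain one against another.

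The table of estimated counts held 132374 transcripts. Of these, 131974 were matched by identifier to GENCODE release M21 (GRCm38, the build called mm10) and summed to 52355 genes, and 400 were left out, which held 0.116% to 0.148% of the counts of a library. Sums were rounded to whole numbers. The library totals were 37560036, 32626784, 54387959 and 48610438 for healthy replicates 1 to 4, 41498395, 42475639, 56320661 and 48371652 for tumor-draining replicates 1 to 4, and 41507421, 42342926, 52059002 and 48448199 for agonist replicates 1 to 4. Between 20964 and 23441 genes had a count of 10 or more in a library. Mitochondrial genes took 1.22% to 4.74% of a library's counts, Malat1 0.417% to 2.46% and the 10 most abundant genes 9.00% to 13.1%. No pair of libraries of a group was identical, and the lowest chi-square per degree of freedom over the 18 pairs within groups was 27.7, above sampling noise.

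Genes were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (robust fit), trimmed mean of M values (TMM) scaling and a count filter (filterByExpr, minimum count 10), which left 23729 genes. All 12 libraries entered each fit with the group as the only term, which left 9 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log CPM used a prior count of 2. With these 4 libraries per group the biological coefficient of variation was 33.9%.

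The title of each library holds a prefix shared by 1 library of each group, which gave the replicate number and was treated as a possible pairing. Deviations from the group means correlated over genes at 0.20 to 0.47 in the 12 pairs of libraries with the same prefix, and at a median of -0.24 (-0.45 to 0.33) in the 36 other pairs, so that the prefix was taken to pair the libraries. In 22 of 24 cases a library correlated best, among the 4 libraries of another group, with that of its own prefix. The group explained 26.5% and the prefix 44.1% of the variance of log CPM. A fit with the prefix as a block, with 6 residual degrees of freedom and a biological coefficient of variation of 20.7%, was therefore set beside the fit without it. What the prefix stands for is not given in the sources used here.

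The 35 gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, a two-sided test and Benjamini-Hochberg adjustment over lists with at least 5 measured genes. The correlation estimated for each list and the fry test were alternatives. Camera compares a list with the other genes, whereas fry tests a list on its own. Members were counted past the gene test adjusted over all genes and adjusted over the list alone. Genes moving back with the agonist were counted as called in opposite directions in the first and second comparisons, which share the tumor-draining libraries, and were set beside 100 simulations of unchanged groups.

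The groups, tests, gene lists, alternatives and rule for named genes were set before the data were examined. For each comparison the rule takes the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean log2 CPM of at least 2 and the same direction in all 4 prefix pairs, without predicted genes, pseudogenes, ribosomal RNA and antigen receptor segments. It also takes up to 3 members with the smallest p of each list called by camera and of a fixed set of lists, and, in every case, Cd40, Itgax, Flt3, Zbtb46, Xcr1, Clec9a, Batf3, Irf8, Il12b, Ccr7, Cd86, Cd80, Cd70 and Cd274. Not every gene that the rule takes from a list is printed, and in 2 comparisons 1 gene of the largest falls is not reported here. Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma voom, limma on log2(TPM + 1) and log2(TPM + 0.1), counts rebuilt from TPM, the block, the 8 libraries of a comparison alone, and each library left out in turn.

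The tests were tried on counts simulated for the comparison of tumor-draining with healthy nodes, over 23180 genes. The counts were drawn with the prefix differences and the spread of the fit with the block, which favors that fit. Changed genes were drawn only from those above a minimum mean count, so recovery of weaker genes was not measured. Of 100 genes changed 2-fold, 36% were recovered by edgeR, 71% by edgeR with the block, 62% by DESeq2 and 33% by limma voom. Of 100 genes changed 4-fold, 85%, 92%, 95% and 82% were recovered. False calls numbered 0, 15, 5 and 0, and camera called 2 of 2 changed and 0 of 40 unchanged lists. The simulated genes varied independently and the unchanged lists were drawn at random. The list result therefore does not show how often camera errs on lists whose genes are correlated.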

Results

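RNA was sequenced from CD11c cells of the mouse inguinal lymph node. CD11c, encoded by Itgax, is an integrin of dendritic cells that some macrophages, natural killer cells and activated lymphocytes also carry. The 12 libraries fell into 3 groups of 4: nodes of healthy mice, nodes draining a subcutaneous KPC tumor, and tumor-draining nodes of mice given a CD40 agonist. KPC tumors are a mouse model of pancreatic carcinoma. CD40 is a receptor of the tumor necrosis factor receptor family on antigen-presenting cells, and agonists of it are used to activate them. Estimated counts totalled 32626784 to 56320661 per library, with a median of 45423645.5, and 23729 genes were tested. Values are means ± SD in CPM, counts scaled to a common library size (n = 4 libraries per group), and log2 fold changes with their standard errors (SE). Gene test p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The largest rises and falls are given among called genes with a mean log2 CPM of at least 2 that moved one way in all 4 prefix pairs, leaving out antigen receptor segments, predicted genes and pseudogenes. Outside the rule for named genes lie Malat1, Mx1, Tcrg-C2, Fcer2a, Klrd1, Scn3a, Ighv1-72, Dram1 and Cdk5r1, which were chosen after their values were seen.

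The sample titles carried a prefix shared by 1 library of each group, used here as the replicate number 1 to 4. The first principal component held 32.7% of the variance, and prefix accounted for 81.4% of its variance and group for 17.3%. The second component held 18.1%, with 61.1% of it by group. Replicates 1 and 2 had higher Malat1 in each group, by 2.71-fold in healthy, 2.48-fold in tumor-draining and 2.27-fold in agonist libraries relative to replicates 3 and 4. Malat1, a nuclear noncoding RNA, also moved with the groups within the prefixes, one way in 4 of 4 pairs each time, with a log2 fold change of -0.65 between tumor-draining and healthy nodes (adjusted p = 0.766; 0.0122 with the prefix as a block) and 0.73 between agonist and tumor-draining nodes (adjusted p = 0.611; 0.00187 with the block). Because the prefix pairs libraries, the value from a fit with the prefix as a block is printed beside a result whose call it changes or whose count of calls it moves by over 1.5 times.

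**Figure D1:**
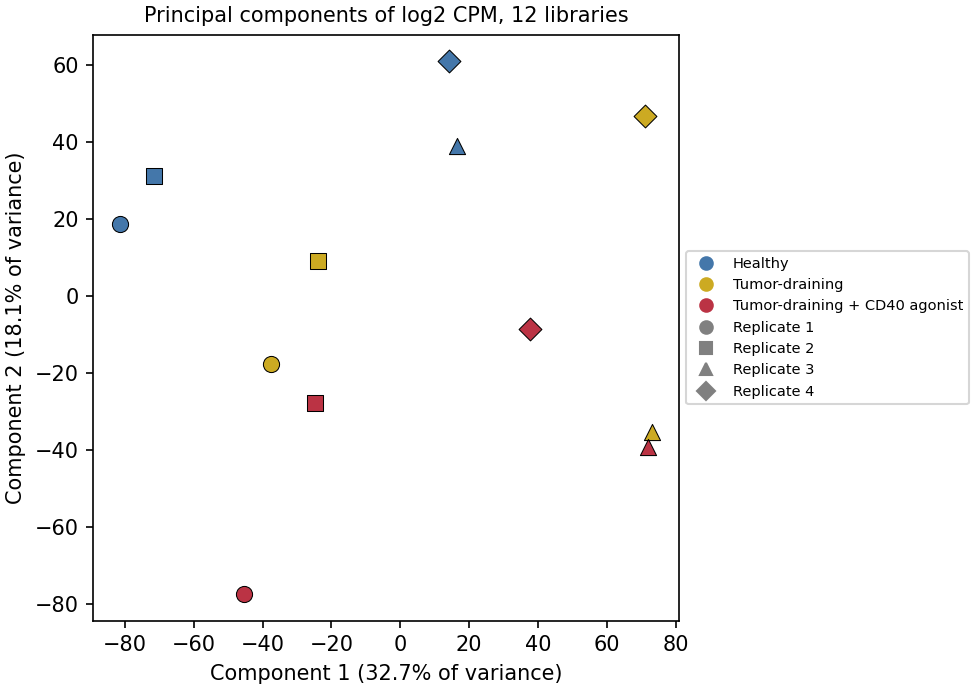
The first 2 principal components of log2 CPM, with the percent of variance on each axis, 1 point per library, colored by group and shaped by replicate number. Replicates 1 and 2 of all 3 groups lie at negative values of the first component and replicates 3 and 4 at positive values.

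The first comparison asked how CD11c cells of a tumor-draining node differ from those of a healthy node. Jchain, which joins polymeric immunoglobulin, rose from 4.58 ± 1.70 to 45.3 ± 28.5 CPM (log2 fold change 3.30, SE 0.46, adjusted p = 0.0253). Socs3, a feedback inhibitor of STAT3 signaling, rose from 21.8 ± 3.96 to 72.4 ± 33.3 CPM (log2 fold change 1.74, SE 0.31, adjusted p = 0.0448). Cd274, which encodes the checkpoint ligand PD-L1, rose from 71.0 ± 4.3 to 116 ± 15.1 CPM (log2 fold change 0.71, SE 0.12, adjusted p = 0.0436). Gzmc, a granzyme, fell from 8.76 ± 3.44 to 2.38 ± 0.75 CPM (log2 fold change -1.88, SE 0.35, adjusted p = 0.0475). Each of these 4 genes moved the same way in 4 of 4 prefix pairs, which the rule for the largest rises and falls required of Jchain and Gzmc. In the GRCm38 annotation Jchain lies on chromosome 5 from 88519809 to 88527891, Socs3 on chromosome 11 from 117966079 to 117970047 and Cd274 on chromosome 19 from 29367455 to 29388095.

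In all, 47 genes passed the threshold, 43 higher and 4 lower (1495 with the prefix as a block, 954 higher and 541 lower). By the rule above, the largest rises besides Jchain were those of Spon1 (log2 fold change 3.17), Acod1 (2.87), which makes the metabolite itaconate, Abca13 (2.70), the growth factor Mdk (2.55), Pram1 (2.18), Tmem132c (2.07), the lectin receptor Clec4a4 (1.99), the interleukin-1 antagonist Il1rn (1.86) and the Notch ligand Dll4 (1.82). Besides Gzmc, the falls were those of the chemokine receptor Cxcr6 (log2 fold change -1.45), the interleukin-23 receptor Il23r (-1.19) and a T cell receptor gamma constant segment, Tcrg-C2 (-3.10). Without tumor-draining replicate 3 the log2 fold change of Spon1 was 2.48 (adjusted p = 0.0743).

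Of 25 type I interferon response genes measured, 1 rose, Oas2, from 2.56 ± 1.04 to 8.44 ± 2.80 CPM (log2 fold change 1.72, adjusted p = 0.0475), and 24 did not pass. Adjusted over the list alone, 20 were higher and 1 lower, and with the prefix as a block 19 were higher and 1, Mx1, lower. Isg15 stood at 6.32 ± 2.08 and 14.6 ± 3.3 CPM (adjusted p = 0.0538; 0.00546 with the block) and Oasl1 at 6.72 ± 2.55 and 14.8 ± 3.5 CPM (adjusted p = 0.0647; 0.0108 with the block). The list as a whole was higher by limma's camera test (median log2 fold change 0.79, adjusted p = 6.94e-21; adjusted p = 0.196 with an estimated correlation). Of 20 interferon gamma response genes, Cd274 alone rose, 8 were higher adjusted over the list alone and 2 with the block, and the list was higher by camera (median log2 fold change 0.48; adjusted p = 0.320 with an estimated correlation).

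Of 9 plasma cell markers, Jchain and Mzb1 rose and 7 did not pass, with 4 higher adjusted over the list alone and 5 with the block. Mzb1 went from 4.69 ± 0.64 to 13.9 ± 3.9 CPM (log2 fold change 1.56, adjusted p = 0.0405), and Ighg2c stood at 3.30 ± 1.66 and 107 ± 108 CPM (adjusted p = 0.0684; 0.00896 with the block). Tumor-draining replicate 3 held Ighg2c at 265 CPM, and without it the log2 fold change was 4.03 in place of 5.01. The list was higher by camera, with adjusted p = 0.196 with an estimated correlation. Of 10 neutrophil markers, Csf3r, the receptor of granulocyte colony-stimulating factor, rose from 14.3 ± 2.0 to 32.4 ± 10.5 CPM (log2 fold change 1.18, adjusted p = 0.0426) and 9 did not pass. Adjusted over the list alone 7 were higher, with the block 5, and the list was higher by camera (median log2 fold change 1.61; adjusted p = 0.196 with an estimated correlation). Of 11 monocyte markers none passed, 3 were higher adjusted over the list alone and 1 with the block, and camera gave a higher list (adjusted p = 0.371 with an estimated correlation).

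None of the 15 T cell markers passed, over all genes or adjusted over the list alone, and with the block 7 were lower, among them Cd3d (8.31 ± 1.54 against 4.58 ± 1.02 CPM, adjusted p = 0.244; 0.0252 with the block) and Lef1 (adjusted p = 0.360; 0.0108 with the block). The list was lower by camera (median log2 fold change -0.70; adjusted p = 0.372 with an estimated correlation). None of the 12 natural killer cell markers passed in either fit, adjusted over the list alone 0 passed without the block and 1 was lower with it, and camera placed that list lower (median log2 fold change -0.68; adjusted p = 0.421 with an estimated correlation). None of the 32 cell cycle genes passed, over all genes or adjusted over the list alone, 18 were higher with the block, and the list was higher by camera (median log2 fold change 0.53; adjusted p = 0.372 with an estimated correlation). Among them Ccne1, a cyclin of S phase entry, stood at 5.23 ± 1.60 and 8.68 ± 1.61 CPM (adjusted p = 0.380; 0.00557 with the block).

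Of 16 costimulatory and coinhibitory molecules, Cd274 rose and 15 did not pass, 3 being higher adjusted over the list alone and 3 with the block. Pdcd1lg2, the second PD-1 ligand, stood at 21.4 ± 2.4 and 35.6 ± 7.1 CPM (adjusted p = 0.0564; 0.00272 with the block). Cd40 was measured at 120.5 ± 12.4 and 126 ± 19.2 CPM (log2 fold change 0.06, SE 0.13, adjusted p = 0.904). Itgax, Flt3, Zbtb46, Batf3, Irf8, Il12b, Ccr7, Cd86, Cd80 and Cd70 were not called, with log2 fold changes from -0.36 (Ccr7) to 0.69 (Cd70) and adjusted p from 0.597 (Cd80) to 0.997 (Flt3), and with the block Cd80 alone of these was called (adjusted p = 0.0358). Of 19 regulatory and tolerogenic genes, Cd274 and Cd200 rose and 17 did not pass, 4 being higher adjusted over the list alone and 4 with the block. Of 23 pattern recognition receptors none passed, 9 were higher adjusted over the list alone and 11 with the block, among them Nod1 (45.3 ± 9.0 and 78.2 ± 13.6 CPM, adjusted p = 0.125; 0.00272 with the block). These 3 lists were higher by camera, with adjusted p = 0.186, 0.255 and 0.320, respectively, with an estimated correlation. The cytokine list (Il1rn of 20 genes rose), the chemokine list (0 of 19), the IL-6 and STAT3 list (Socs3 of 15) and the glycolysis list (0 of 18) were also higher by camera, with adjusted p = 0.384, 0.443, 0.372 and 0.539 with an estimated correlation. Adjusted over each list alone 4, 4, 2 and 0 of their members were higher, and with the block 2, 2, 4 and 4.

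No dendritic cell subset marker was called lower without the block, and with it 1 of 7 Langerhans cell markers was (0 without the block and 3 with it adjusted over the list alone; camera adjusted p = 0.0755). None of the 15 type 1 conventional dendritic cell markers passed in either fit (camera adjusted p = 0.0648), and Xcr1 stood at 273 ± 52.3 and 198 ± 51.6 CPM (log2 fold change -0.46, SE 0.29, adjusted p = 0.745) and Clec9a at 119 ± 12.9 and 91.4 ± 13.3 CPM (adjusted p = 0.665). Of 15 type 2 markers, Clec4a4 rose and 14 did not pass, with 1 higher adjusted over the list alone and 4 with the block. None of 14 MHC class II and none of 17 MHC class I presentation genes passed, over all genes or adjusted over each list alone, and 3 class II genes were higher with the block. With the block, camera also called the type 1 list lower (adjusted p = 0.0377) and the lists of B cell markers (0.0377), CD40 and NF-kB targets (0.0185), MHC class II presentation (0.0391), dendritic cell development (0.0185) and the unfolded protein response (0.0278) higher, of which 0 passed with an estimated correlation.

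With the prefix as a block, 1495 genes passed (954 higher, 541 lower), including all 47. Without the block 1842 genes had an unadjusted p under 0.05, limma voom called 1 gene and DESeq2 370, and leaving out 1 library gave 0 calls (without healthy replicate 1, 3 or 4), 1 (healthy 2), 6, 27, 3 and 101 (tumor-draining 1, 2, 3 and 4), so the unblocked count depended on each library.

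The second comparison asked what the CD40 agonist changed in the tumor-draining node. The genes that rose included members of the lists for mature dendritic cells, interferon responses and cytokines, and those that fell included markers of dendritic cell subsets, MHC class II genes and genes of cholesterol synthesis. Ccr7, the receptor that guides dendritic cells to and within lymph nodes, rose from 236 ± 35.4 to 762 ± 139 CPM (log2 fold change 1.69, SE 0.22, adjusted p = 0.00139). Gbp5, an interferon-induced guanylate-binding protein, rose from 76.2 ± 6.4 to 209.9 ± 19.5 CPM (log2 fold change 1.46, SE 0.17, adjusted p = 0.000650). Cd209a, a lectin of monocyte-derived and type 2 dendritic cells, fell from 183 ± 50.3 to 28.7 ± 15.0 CPM (log2 fold change -2.67, SE 0.34, adjusted p = 0.00144). Each moved the same way in 4 of 4 prefix pairs, which the rule for the largest falls required of Cd209a. In the GRCm38 annotation Ccr7 lies on chromosome 11 from 99144196 to 99155077, Gbp5 on chromosome 3 from 142493978 to 142522344 and Cd209a on chromosome 8 from 3743397 to 3748984.

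A total of 635 genes passed, 438 higher and 197 lower (3161 with the prefix as a block, 1600 higher and 1561 lower). By the rule above, the largest rise was that of Cryaa, a small heat shock protein first known from the lens, from 1.98 ± 0.48 to 20.2 ± 4.8 CPM (log2 fold change 3.35, adjusted p = 3.48e-05). It was followed by Selenom (log2 fold change 2.79), the metallothionein Mt2 (2.64), Fabp1 (2.55), the serpin Serpinb9b (2.41), Gbp10 (2.26; adjusted p = 0.0314, and 0.0724 with the block), the granzymes Gzmb (2.23) and Gzma (2.15), Ramp3 (2.15) and Cd5l (2.05). Large falls included those of the oxysterol hydroxylase Cyp7b1 (log2 fold change -3.06), Cd209d (-3.01), Cd209a, Pi16 (-2.66), Aqp3 (-2.27), Chil5 (-2.24), Apod (-2.16), Cacna1i (-2.07) and the histamine receptor Hrh1 (-1.99). Without agonist replicate 4 the log2 fold changes of Cd209d, Pi16 and Aqp3 were -3.99, -3.33 and -3.04, and without tumor-draining replicate 3 that of Gbp10 was 2.98. Cd209a, Cd209d, the Gbp genes and the granzymes have close paralogs, between which estimated counts can be divided with error.

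Of 20 interferon gamma response genes, 12 rose, none fell and 8 did not pass, with 17 higher and 1 lower adjusted over the list alone and 14 and 1 with the block. Gbp2 rose from 221 ± 54.8 to 542 ± 25.2 CPM (log2 fold change 1.29, adjusted p = 0.00118) and Gbp6 from 25.2 ± 9.6 to 77.4 ± 13.1 CPM (log2 fold change 1.62). The list was higher by camera (median log2 fold change 1.01, adjusted p = 1.95e-17; adjusted p = 0.118 with an estimated correlation). Of 25 type I interferon response genes, 7 rose and 18 did not pass, with 20 higher adjusted over the list alone and 15 with the block. Oasl1 rose from 14.8 ± 3.5 to 44.0 ± 6.9 CPM (log2 fold change 1.57, adjusted p = 0.00313) and Ifi44 from 10.8 ± 1.6 to 23.5 ± 2.5 CPM (log2 fold change 1.12). That list had a median log2 fold change of 0.72 and adjusted p = 0.180 with an estimated correlation.

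Of 20 migratory and mature dendritic cell genes, 7 rose and 13 did not pass, with 15 higher and 1 lower adjusted over the list alone and 15 higher with the block. With Ccr7 these included Serpinb6b (349.7 ± 54.3 to 805 ± 120 CPM, log2 fold change 1.20), Ccl22 (577 ± 175 to 1532 ± 482 CPM, log2 fold change 1.41) and Cd200 (42.2 ± 4.0 to 75.8 ± 6.3 CPM, log2 fold change 0.85). Of 20 cytokine genes 7 rose, among them Il6 (0.72 ± 0.18 to 4.43 ± 1.44 CPM, log2 fold change 2.61), Il27 (log2 fold change 1.48), its partner subunit Ebi3 (1.07), and Il12b, the shared p40 subunit of IL-12 and IL-23 (39.0 ± 7.2 to 70.7 ± 15.8 CPM, log2 fold change 0.86, adjusted p = 0.0340). Adjusted over the list alone, 10 cytokine genes were higher and 1 lower, and with the block 9 were higher. Of 19 chemokine genes 6 rose, with Ccl5 (201 ± 44.3 to 785 ± 206 CPM, log2 fold change 1.96) and Xcl1 (log2 fold change 1.68) beside Ccl22, and 10 were higher and 1 lower adjusted over the list alone and 10 higher with the block. These 3 lists were higher by camera, with adjusted p = 0.180, 0.118 and 0.180, respectively, with an estimated correlation.

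Of 21 CD40 and NF-kB target genes 4 rose, including Ebi3, the survival factor Bcl2l1 (33.3 ± 3.5 to 60.2 ± 8.8 CPM, log2 fold change 0.85) and the adaptor Traf1 (399 ± 26.2 to 644 ± 45.5 CPM, log2 fold change 0.69), and 11 were higher and 1 lower adjusted over the list alone, against 13 and 2 with the block. Of 16 costimulatory and coinhibitory molecules 2 rose, Cd274 (116 ± 15.1 to 194.5 ± 17.9 CPM, log2 fold change 0.75) and the OX40 ligand Tnfsf4 (2.80 ± 1.03 to 11.6 ± 4.4 CPM, log2 fold change 2.05), with 6 higher and 3 lower adjusted over the list alone and 8 and 3 with the block. The classical ligands of CD28 were not called: Cd86 stood at 202 ± 9.7 and 235 ± 30.7 CPM (adjusted p = 0.498) and Cd80 at 25.5 ± 5.2 and 36.3 ± 10.2 CPM (adjusted p = 0.278; 0.0138 with the block). Cd70 stood at 0.75 ± 0.23 and 2.18 ± 0.50 CPM (adjusted p = 0.0651; 0.0159 with the block), and Cd40 itself at 126 ± 19.2 and 154 ± 6.9 CPM (log2 fold change 0.29, SE 0.13, adjusted p = 0.337; 0.0193 with the block). Both lists were higher by camera, with adjusted p = 0.207 and 0.180 with an estimated correlation, and the costimulatory list did not pass camera with the block (adjusted p = 0.0634).

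Of 17 MHC class I presentation genes, 4 rose and 13 did not pass, with 10 higher adjusted over the list alone and 13 with the block. Among them were Nlrc5, the transactivator of MHC class I genes (304 ± 37.7 to 446 ± 20.4 CPM, log2 fold change 0.55), Tapbpl (log2 fold change 0.70) and the immunoproteasome subunit Psmb10 (0.63). Of 14 MHC class II presentation genes, 3 fell and 11 did not pass, with 9 lower and 1 higher adjusted over the list alone and 11 lower with the block. March1, a ubiquitin ligase that acts on surface MHC class II, fell from 245 ± 34.8 to 138 ± 21.4 CPM (log2 fold change -0.83), H2-Ob from 140.4 ± 10.6 to 78.5 ± 19.5 CPM (-0.84) and H2-DMb1 from 387 ± 73.4 to 228 ± 13 CPM (-0.77). H2-Ob, a chain of H2-O, and March1 are known to limit class II presentation, whereas H2-DMb1 is a chain of the peptide-loading molecule H2-M. The class I list was higher and the class II list lower by camera, both with adjusted p = 0.228 with an estimated correlation.

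Of 15 type 1 conventional dendritic cell markers, 2 fell, the dead-cell receptor Clec9a (91.4 ± 13.3 to 52.5 ± 15.7 CPM, log2 fold change -0.80, adjusted p = 0.0335) and Naaa (699 ± 193 to 317 ± 102 CPM, log2 fold change -1.14), and with the block 9 were lower and 1, Batf3, higher. Xcr1 stood at 198 ± 51.6 and 98.1 ± 44.2 CPM (adjusted p = 0.0886; 0.0140 with the block), Batf3 at 36.0 ± 7.3 and 52.2 ± 4.5 CPM (adjusted p = 0.0815; 0.00264 with the block) and Irf8 at 870.5 ± 321 and 819 ± 201 CPM (adjusted p = 0.969). Of 15 type 2 markers 5 fell, including Cd209a, Mgl2 (124 ± 49.1 to 43.3 ± 12.8 CPM, log2 fold change -1.52), a paralog of Clec10a, and Clec10a (93.8 ± 24.6 to 40.4 ± 6.6 CPM, log2 fold change -1.22), and 8 were lower and 1 higher with the block. Of 15 plasmacytoid dendritic cell markers 2 fell, Bcl11a (107 ± 15.1 to 52.3 ± 8.1 CPM, log2 fold change -1.04) and Atp1b1 (-1.15), and 9 were lower with the block. With p adjusted over the list alone, list by list, 10, 6 and 4 were lower, and 1 type 1 marker was higher. The 3 lists were lower by camera, with adjusted p = 0.228, 0.180 and 0.480, respectively, with an estimated correlation. Of the genes shared by dendritic cells, Itgax stood at 968 ± 188 and 731 ± 130 CPM (adjusted p = 0.431; 0.0260 with the block), Flt3 at 677 ± 136 and 462 ± 100 CPM (adjusted p = 0.187; 0.00174 with the block) and Zbtb46 at 178 ± 18.5 and 157 ± 17.9 CPM (adjusted p = 0.652; 0.118 with the block).

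Markers of other cell types moved beside these groups. Of 15 macrophage markers, 4 rose, among them Siglec1 (46.1 ± 8.2 to 169 ± 68.9 CPM, log2 fold change 1.88) and Marco (23.2 ± 5.0 to 66.6 ± 16.8 CPM, log2 fold change 1.52), and Cd163 fell (log2 fold change -1.51). Of 12 natural killer cell markers, Gzma, Gzmb and Ccl5 rose and Klrd1 fell, and those that rose are cytotoxic and secreted products that T cells also make. Adjusted over each list alone, 9 were higher and 3 lower, and 7 higher and 1 lower, respectively. With the block 5 macrophage markers were higher and 2 lower, and 7 natural killer cell markers higher and 1 lower. Both lists were higher by camera, with adjusted p = 0.213 and 0.228 with an estimated correlation. None of the 15 T cell markers and none of the 9 plasma cell markers passed, and 1 of 14 B cell markers, Fcer2a, rose. Adjusted over each list alone, 1 B cell marker was higher and 1 lower and none of the others passed, and with the block 3 B cell markers were higher and 4 lower and 1 T cell marker was lower.

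Of 19 cholesterol biosynthesis genes, 7 fell, none rose and 12 did not pass, with 12 lower adjusted over the list alone and 14 with the block. Idi1 fell from 75.7 ± 6.5 to 44.4 ± 4.3 CPM (log2 fold change -0.77, adjusted p = 0.0103), Sc5d from 30.1 ± 4.5 to 19.5 ± 1.9 CPM (-0.63) and Msmo1 from 34.1 ± 1.6 to 24.6 ± 1.5 CPM (-0.47). The list was lower by camera (median log2 fold change -0.49, adjusted p = 6.26e-11; adjusted p = 0.180 with an estimated correlation). Camera also called 6 further lists. The pro-apoptotic (Tnfsf10 of 20 rose), anti-apoptotic (Bcl2l1 of 12), regulatory (3 of 19, among them Cd274, Cd200 and Axl) and glycolysis (Pfkfb3 of 18) lists were higher, with adjusted p = 0.207, 0.180, 0.272 and 0.739 with an estimated correlation. When adjusted over the list alone, 3, 6, 7 and 2 of their members were higher and 0, 1, 2 and 0 lower, and with the block 6, 8, 6 and 6 were higher and 0, 2, 3 and 1 lower. The cell cycle list (0 of 32) and the unfolded protein response list (0 of 16) were lower, with adjusted p = 0.700 and 0.562 with an estimated correlation. When adjusted over the list alone, 0 of their members passed, and with the block 5 cell cycle genes were lower, and 7 unfolded protein response genes were lower and 1 higher. The regulatory list did not pass camera with the block (adjusted p = 0.165).

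With the prefix as a block, 3161 genes passed (1600 higher, 1561 lower), 631 of the 635 among them, and upper-quartile scaling gave 973 genes with 58.7% higher where the main scaling gave 69.0%. Leaving out tumor-draining replicate 2, 3 or 4 left 323, 422 and 336 genes and agonist replicate 3 or 4 left 362 and 360, and DESeq2 called 1186 genes and limma on log2(TPM + 1) 271.

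**Figure D2:**
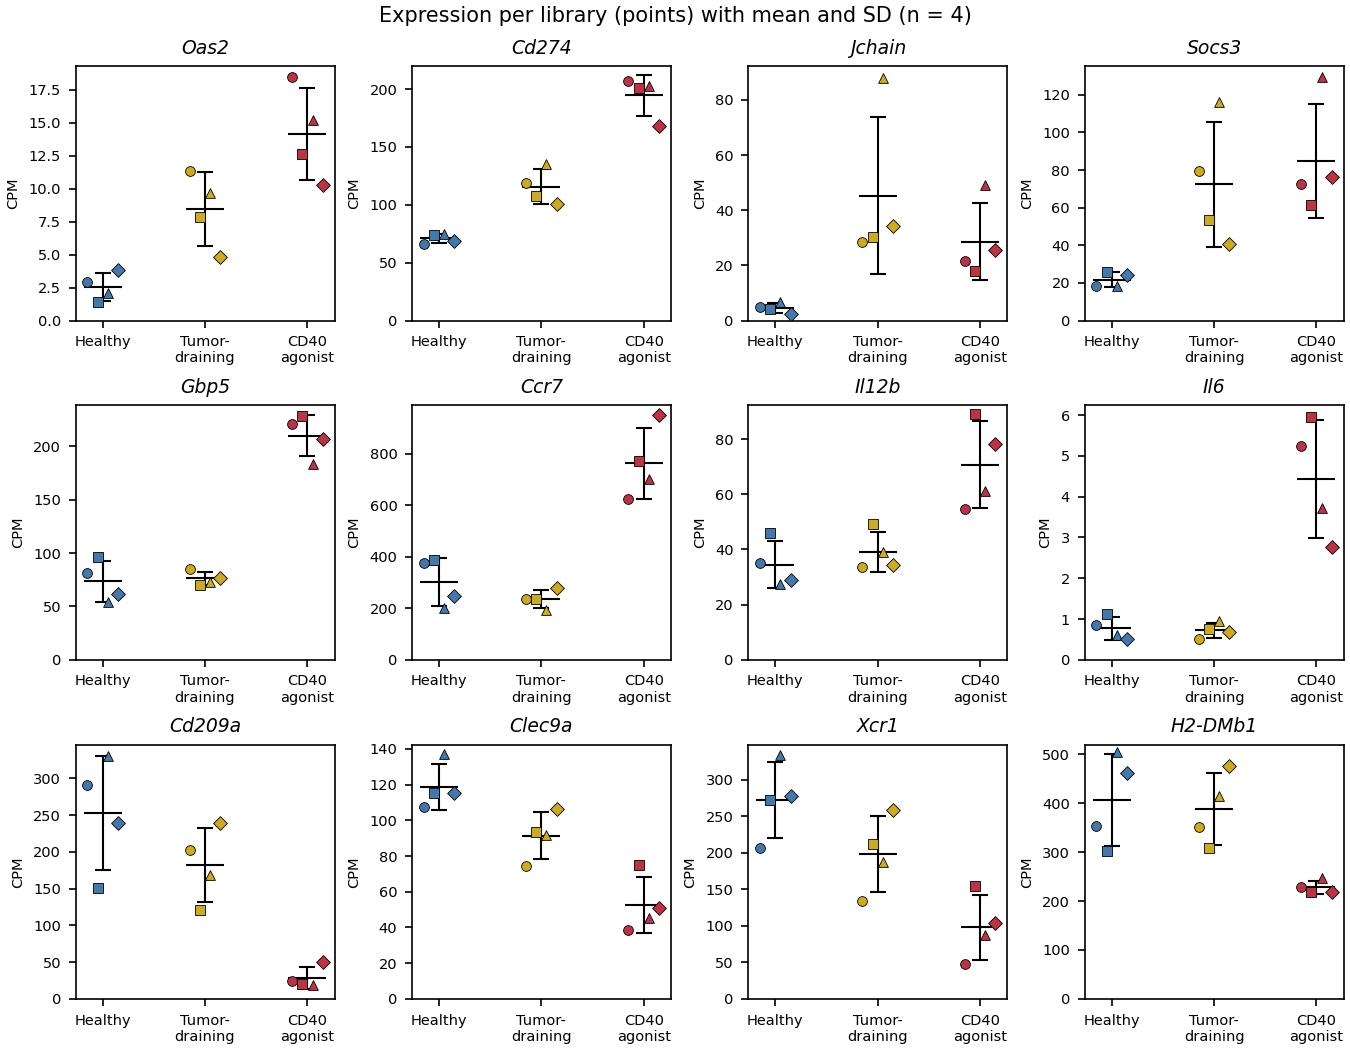
CPM of 12 genes on linear axes from 0, with 1 point per library, shaped by replicate number as in the plot of components, and the mean with SD of the 4 libraries of each group. Ccr7 lies between 625 and 949.7 CPM in the agonist libraries and between 193 and 279.6 CPM in the tumor-draining libraries.

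The third comparison set the agonist-treated tumor-draining nodes against healthy nodes, and held the largest number of changed genes, 1490, with 1009 higher and 481 lower (4781 with the prefix as a block, 2774 higher and 2007 lower). Nos2, the inducible nitric oxide synthase, rose from 0.35 ± 0.12 to 9.13 ± 10.5 CPM (log2 fold change 4.71, SE 1.03, adjusted p = 0.0175; log2 fold change 3.48 without agonist replicate 1), and Acod1 from 1.03 ± 0.41 to 25.2 ± 11.2 CPM (log2 fold change 4.62, SE 0.47, adjusted p = 0.000130). Cd274 rose from 71.0 ± 4.3 to 194.5 ± 17.9 CPM (log2 fold change 1.45, SE 0.13, adjusted p = 2.34e-05). Xcr1, the chemokine receptor of type 1 dendritic cells, fell from 273 ± 52.3 to 98.1 ± 44.2 CPM (log2 fold change -1.47, SE 0.29, adjusted p = 0.00742). Each moved the same way in 4 of 4 prefix pairs, which the rule for the largest rises required of Nos2 and Acod1. In the GRCm38 annotation Nos2 lies on chromosome 11 from 78920787 to 78960254 and Xcr1 on chromosome 9 from 123852315 to 123862029.

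By the rule above, further rises were those of Retnlg (log2 fold change 4.44), Chil3 (4.27), Abca13 (4.17), the formyl peptide receptor Fpr2 (3.81), the acute phase gene Saa3 (3.62), Cryaa (3.58), Spon1 (3.55) and Ramp3 (3.45). Large falls included those of Cd209e (log2 fold change -4.76), Cd209d (-3.72), Ngfr (-3.67), Aqp3 (-3.47), Cd209a (-3.14), langerin Cd207 (-2.94), Pi16 (-2.86), Hepacam2 (-2.64) and the scavenger receptor Cd163 (-2.51). Without agonist replicate 4 the log2 fold changes of Cd209e, Cd209d, Ngfr, Aqp3 and Pi16 were -6.40, -4.72, -5.25, -4.26 and -3.55. That of Saa3 was 2.56 without agonist replicate 1, that of Chil3 5.10 without healthy replicate 4, and that of Retnlg 5.16 without healthy replicate 3 and 3.75 without agonist replicate 3, where it was not called (adjusted p = 0.0550 and 0.0758).

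Of 25 type I interferon response genes 22 rose and 3 did not pass, and of 20 interferon gamma response genes 16 rose and 4 did not pass. Oasl1 rose from 6.72 ± 2.55 to 44.0 ± 6.9 CPM (log2 fold change 2.71) and Gbp2 from 167 ± 14.0 to 542 ± 25.2 CPM (log2 fold change 1.70). Of 20 cytokine genes 10 rose, of 19 chemokine genes 9 and of 16 costimulatory and coinhibitory molecules 5, among them Il12b (log2 fold change 1.04), Cxcl10 (2.40), Cd70 (2.23) and Cd80 (0.98, adjusted p = 0.0107). Adjusted over each list alone, 22, 18, 14, 15 and 8 were higher, and with the block 23, 18, 13, 10 and 8 were higher and 0, 1, 0, 0 and 1 lower. These 5 lists were higher by camera, with adjusted p = 0.0571, 0.0433, 0.0433, 0.0571 and 0.0433, respectively, with an estimated correlation, and the 3 at 0.0433 were the only lists of the 3 comparisons to pass with one. With the block and an estimated correlation, 0 lists passed, although 23 passed the block with the preset correlation and 23 by fry.

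Of 15 type 1 dendritic cell markers 8 fell, among them Clec9a (119 ± 12.9 to 52.5 ± 15.7 CPM, log2 fold change -1.18), Naaa (-1.40) and Tlr3 (-1.30), and 11 were lower and 1 higher adjusted over the list alone. Of 15 type 2 markers, 6 fell, including Mgl2 (-2.18) and Clec10a (-1.39), and Clec4a4 rose. The 14 MHC class II presentation genes held 5 that fell and 1, Lgmn, that rose (log2 fold change 1.21). The 15 T cell markers held 5 that fell, among them Themis (log2 fold change -1.27) and Lef1 (-1.06). The 19 cholesterol biosynthesis genes held 7 that fell. Called only with the block were Flt3 (log2 fold change -0.56, adjusted p = 0.122; 0.000872 with the block), Zbtb46 (-0.31, 0.197; 0.00913), Cd40 (0.36, 0.138; 0.00521), Batf3 (0.53, 0.0513; 0.00186) and Cd86 (0.42, 0.0523; 0.00516), and in neither fit Itgax (-0.19, adjusted p = 0.739) and Irf8 (-0.27, 0.728). Per list, adjusted over the list alone, 7, 8, 7 and 13 members of these 4 lists were lower, with 3, 1, 0 and 0 higher. With the block 11, 9, 9, 12 and 15 members of the 5 lists were lower and 1, 4, 1, 0 and 0 higher. The 5 lists were lower by camera, with adjusted p = 0.221, 0.317, 0.431, 0.256 and 0.206, respectively, with an estimated correlation, and the type 2 list did not pass with the block (adjusted p = 0.0529).

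Of 20 migratory and mature dendritic cell genes 9 rose, of 21 CD40 and NF-kB targets 8, of 17 MHC class I genes 4 and of 19 regulatory genes 6, with 1 regulatory gene lower. Ccr7 rose from 303.5 ± 93.0 to 762 ± 139 CPM (log2 fold change 1.33) and B2m, the light chain of MHC class I, from 2350 ± 279 to 3530 ± 470 CPM (0.59). Of other cell types, 8 of 15 macrophage markers rose and 2 fell, 3 of 10 neutrophil markers rose, and 3 of 9 plasma cell markers rose. Adjusted over each list alone, 14, 12, 10, 8, 10, 7 and 6 members of these 7 lists were higher, with 1, 0, 0, 2, 3, 0 and 0 lower. The 7 lists were higher by camera, with adjusted p = 0.149, 0.136, 0.254, 0.128, 0.206, 0.172 and 0.206, respectively, with an estimated correlation. With the block 14, 15, 13, 8, 10, 9 and 5 of their members were higher and 1, 0, 0, 2, 2, 0 and 0 lower.

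Camera called 7 further lists. The glycolysis (7 of 18 rose), IL-6 and STAT3 (3 of 15), pro-apoptotic (3 of 20), anti-apoptotic (5 of 12), pattern recognition receptor (7 of 23 rose and 2 fell) and cell cycle (0 of 32) lists were higher, with adjusted p = 0.314, 0.317, 0.128, 0.0571, 0.317 and 0.713 with an estimated correlation. Adjusted over each list alone 11, 5, 6, 5, 10 and 0 of their members were higher and 1, 0, 0, 0, 2 and 0 lower, and with the block 11, 6, 10, 7, 11 and 5 were higher and 1, 2, 1, 1, 2 and 0 lower. The plasmacytoid dendritic cell list (Bcl11a of 15 fell) was lower, with adjusted p = 0.640 with an estimated correlation, and 3 members were lower adjusted over the list alone and 8 lower and 2 higher with the block. Among these lists, Gapdh, a glycolytic enzyme, rose from 314 ± 74.8 to 571 ± 107 CPM (log2 fold change 0.86) and Cebpb, a transcription factor, from 2.59 ± 0.98 to 10.2 ± 3.8 CPM (log2 fold change 1.98). Bcl2a1b and Bcl2a1d, near-identical paralogs whose counts are uncertain one from the other, rose by log2 fold changes of 1.18 and 0.87.

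With the prefix as a block, 4781 genes passed (2774 higher, 2007 lower), 1477 of the 1490 among them, and upper-quartile scaling gave 52.5% higher where the main scaling gave 67.7%. Leaving out healthy replicate 3 or agonist replicate 3 left 829 and 891 genes, and limma on log2(TPM + 1) called 730.

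**Figure D3:**
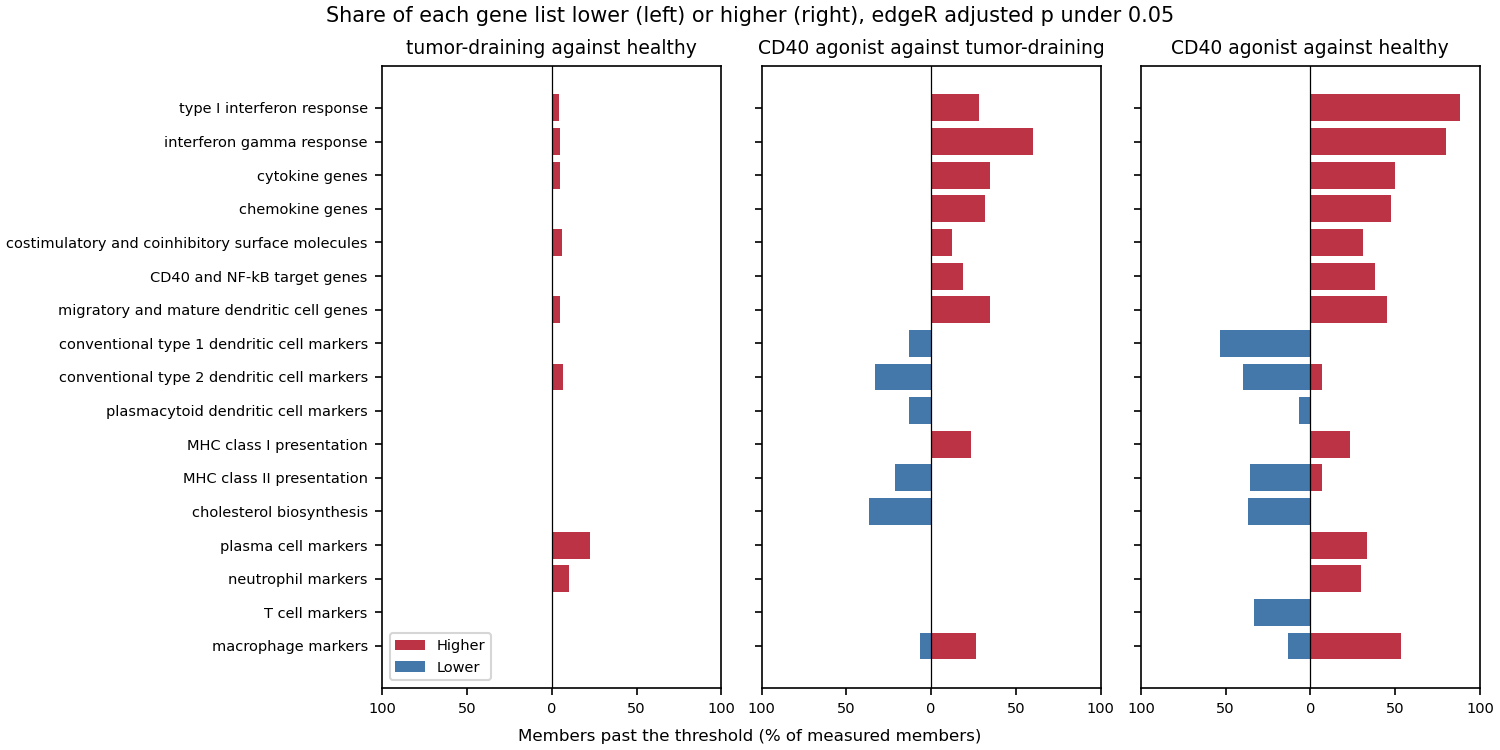
Bars give the percent of each list's measured members that were higher (red, to the right) or lower (blue, to the left) at an edgeR adjusted p under 0.05, for 17 of the 35 lists in each comparison. The fit was that without the prefix as a block. In the comparison of agonist with healthy nodes, 22 of 25 type I interferon genes lie to the right and 8 of 15 type 1 dendritic cell markers to the left.

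A final count asked whether genes changed in tumor-draining nodes moved back toward the healthy level with the agonist. Of the 47 genes called between tumor-draining and healthy nodes, 5 were called in the opposite direction between agonist and tumor-draining nodes and 6 in the same direction. The 5 were Il23r, Gzmc, Tcrg-C2, Scn3a and the immunoglobulin segment Ighv1-72, and the 6 were Cd274, Cd200, Acod1, Ramp3, Dram1 and Cdk5r1. Il23r fell from 5.31 ± 1.30 to 2.32 ± 0.45 CPM with the tumor and stood at 7.62 ± 0.92 CPM with the agonist. Against healthy nodes, 37 of the 47 were called in the same direction with the agonist. The 47 were selected for differing from these same healthy libraries, which favors such calls, and no expected value was computed. Independent lists of 47 and 635 genes, as in the first and second comparisons, would share 0.431 opposite and 0.827 same-direction calls. In 100 simulations of unchanged groups that share the tumor-draining libraries, 0 genes were called in the first comparison and at most 1 in the second, so that their 0 opposite calls give no value for lists of 47 and 635 genes. With the prefix as a block the counts were 290 opposite and 156 same-direction calls, beside 99.2 and 99.9 for independent lists and at most 2 opposite in the simulations, which called at most 5 and 7 genes. Malat1 was among the 290.

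The correlation of fold changes across genes, which are not independent replicates, was -0.26, beside a simulated -0.50 from the shared libraries alone. Its covariance was -0.083, beside a simulated -0.068 (-0.082 to -0.057), a difference of -0.015. The simulated genes varied independently, so this range leaves out shifts shared by many genes of a library. The difference therefore decides nothing. When the 4 tumor-draining libraries were split into sets of 2 that each served 1 comparison, each of 6 splits gave 0 opposite calls, but the first comparison then called 0, 219, 0, 36, 2 and 24 genes, so that in 2 of the splits none could be opposite. Same-direction calls numbered 32 in the split that set tumor-draining replicates 1 and 3 against healthy nodes and at most 1 in the others. Each set of 2 holds only 2 of the prefixes but was compared with all 4 libraries of another group. Without the block, a prefix difference therefore enters both fold changes with the same sign. This favors same-direction calls and a positive covariance, so the unblocked splits do not decide whether genes moved back. The median covariance was 0.0067 (-0.055 to 0.15). With the block the medians were 17 opposite and 20.5 same-direction calls. The opposite count ranged from 0 to 3 when 1 library was left out.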

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

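All tests of other splits except that of genes moving back, and all tests weighed here except those of library size and of GC content and length, were chosen after the result was seen.

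The libraries divided by prefix more than by group. Between replicates 1 and 2 and replicates 3 and 4 of all 3 groups, 10910 genes were called by edgeR (5640 higher and 5270 lower in replicates 1 and 2). This fit took libraries of a prefix as independent, although their deviations from the group means correlated at 0.20 to 0.47. The contrast varies only between the 4 prefixes, 2 on each side. It also follows a division seen on the first principal component of the same data. The number of calls is therefore inflated, and the counts below share this fault and serve only for comparison with it. The total count as such and GC content or length bias are argued against as the whole cause. After all libraries were thinned to the smallest, 10110 genes were called. After a trend on GC content and transcript length was removed, 11065 were called (99.92% of genes had both values). Totals were lower in replicates 1 and 2 than in 3 and 4 in each group, and edgeR already scales for them. Thinning therefore cannot address a cause that goes with the total, such as a difference in library preparation. More noncoding or unspliced RNA in replicates 1 and 2 stays open as a candidate explanation, since the median log2 difference of 4750 noncoding genes exceeded that of 15823 protein-coding genes by 0.838 in healthy, 0.999 in tumor-draining and 0.842 in agonist libraries. No biological explanation was tested, and what the shared prefix stands for is not given in the sources used here.

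Some immunoglobulin and plasma cell genes were called higher in tumor-draining than in healthy nodes, and immunoglobulin genes were not tested as a list. Of 9 plasma cell markers 2 were called, and the list passed camera but not with an estimated correlation (adjusted p = 0.196). Ighg1, chosen after its values were seen, stood at 2.73 ± 2.23 CPM in healthy and 185 ± 149 CPM in tumor-draining nodes (n = 4 each, log2 fold change 6.08, edgeR adjusted p = 0.0493). Without tumor-draining replicate 3, which held 401 CPM, these were 5.37 and 0.124, and Ighg1 was not called without any 1 of the 8 libraries. Igkc, chosen in the same way, stood at 75.1 ± 24 and 331 ± 213 CPM (adjusted p = 0.0915, and 0.0109 with the block). B cells of every kind among the sorted cells, looked for as a median log2 fold change of at least 1, are argued against at that size. The 14 B cell markers had a median of 0.0737, below the bound of 0.5. Their pair medians were 0.11 ± 0.28 (SD, 4 pairs). These lay below 1 by more than 2 times the SD but below 0.5 by less, so a smaller gain of B cells is not excluded. With the block 3 of the 14 were higher, and camera called the list higher (adjusted p = 0.0377, but 0.618 with an estimated correlation). Plasma cells or their RNA may contribute and stay open. How far the sort removed them is not given in the sources used here. The unfolded protein response list also holds Xbp1, 1 of the 7 plasma cell markers other than immunoglobulin genes. These 7 had a median log2 fold change of 0.439, with 3 of them higher with the block. Their pair medians were 0.31 ± 0.22 (SD, 4 pairs), so that the median lay under its bound of 0.5 by less than this spread, and the requirement that it lie beyond the spread was set after the value was seen. A response of B lineage cells to the tumor, the biological explanation that the design gives, was not tested apart from this and cannot be told apart from plasma cell RNA carried through the sort.

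The lists of MHC class II genes and of type 1, type 2 and plasmacytoid dendritic cell markers were lower by camera with the agonist than in tumor-draining nodes, but none passed with an estimated correlation (adjusted p = 0.228, 0.228, 0.180 and 0.480). Of their members 3 of 14 and 2, 5 and 2 of 15 were called lower by edgeR, and with the block 11, 9, 8 and 9 were lower and 0, 1, 1 and 0 higher. Among class II genes that were called only with the block, H2-Aa stood at 7747 ± 1017 and 5076 ± 499.8 CPM (n = 4 each, edgeR adjusted p = 0.105; 0.00437 with the block) and Cd74 at 15239 ± 4138 and 9904 ± 1934 CPM (adjusted p = 0.258; 0.00583 with the block). A lower share of dendritic cells, with all other cell types gaining alike, was weighed by whether the lists of other types rose alike. They did not in 2 of 6 pairs of lists. Macrophage markers exceeded B cell markers by 0.987 ± 0.220 (SD, 4 pairs). Natural killer cell markers exceeded T cell markers by 1.05 ± 0.45, and each difference lay beyond 2 times its SD. The other 4 of the 6 pairs of lists stayed within that bound, macrophage against T cell markers at 1.12 ± 0.74, and all 6 were compared only after that difference was seen. Pair medians were 0.95 ± 0.41 for macrophage, 0.88 ± 0.47 for natural killer, -0.04 ± 0.31 for B and -0.17 ± 0.38 for T cell markers. Regulation of the listed genes within cells was not tested and could part the lists as well, so this does not decide whether other types gained alike. A lower share of dendritic cells, with equal or unequal gains of other types, therefore stays open, as does a gain or a change of macrophages or natural killer cells in particular. Of genes shared by dendritic cells, Flt3 and Itgax were lower with the block (log2 fold change -0.56 and -0.39, edgeR adjusted p = 0.00174 and 0.0260). Zbtb46 was not called (-0.19, adjusted p = 0.118). Dendritic cell maturation, in which MHC class II transcription is known to be shut down, stays open too. Ciita, the regulator of that transcription, had a log2 fold change of -0.82 with the prefix as a block (edgeR adjusted p = 0.000327). Without the block it was -0.81 (adjusted p = 0.154). Ciita is itself a member of the MHC class II list, and a lower share of dendritic cells would lower it as well. Its fall therefore does not tell these explanations apart.

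Of the 35 splits of 8 libraries into groups of 4, 2 gave as many genes as the 47 called between tumor-draining and healthy nodes, the highest other giving 4159, and 2 gave as many as the 635 between agonist and tumor-draining nodes, the highest other giving 2426, so chance could not be excluded this way. In both cases the other split set replicates 1 and 2 against 3 and 4, which points to a structure of the samples, and with the prefix as a block the real splits gave 1495 and 3161 genes. For agonist against healthy nodes 1 of 35 splits, the real one, gave 1490 genes and the highest other 1. Only 8 of these splits part all 4 prefix pairs, and the others mix the prefix difference into the comparison. Because the prefix pairs the libraries, chance was not excluded this way either. For gene lists chance could not be excluded: 16, 3 and 2 of 35 splits gave as many as the 15, 21 and 24 lists called, with 25, 23 and 25 in the highest other. For the 5 genes moving back the regroupings decide nothing: 1 of 100, the real one, gave as many and the highest other 1, but 98 of the 99 others called no gene in at least 1 of the comparisons. The 8 splits that part all 4 prefix pairs are too few for a share under 0.05; with the block the real splits gave 1495, 3161 and 4781 genes and the highest others 0, 1 and 0, and without it 47, 635 and 1490 genes and 0, 0 and 0. Over those 8 splits the lists numbered 15, 21 and 24 in the real split and 20, 19 and 23 in the highest other.

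In 16 of 468 sets of 4 libraries tested, 1 library stood far from the others by Dixon's test. It compares the gap to the nearest library with the range of the 4. For genes, gap and range were taken on log2 CPM, so the CPM values printed below do not give the gaps directly. Chance gives about 1 in 20 such sets, or 23.4 here. In agonist replicate 1 the 7S RNAs took 1.31% of counts beside 0.433% to 0.483% in the other agonist libraries, a gap of 0.944 of the range. Bcl11a in the same library stood at 40.3 CPM beside 54.6 to 57.3 CPM (gap 0.864). In agonist replicate 3, H2-Aa stood at 5820 CPM beside 4758 to 4909 CPM (gap 0.845) and Mdk at 11.3 beside 4.82 to 5.49 CPM (gap 0.848). Agonist replicate 4 held Ccl22 at 2251 beside 1216 to 1344.5 CPM (gap 0.837), Cd274 at 168 beside 201 to 207 CPM (gap 0.868) and Tcrg-C2 at 1.18 beside 0.489 to 0.549 CPM (gap 0.873). Tumor-draining replicate 2 held Ccr2 at 267 beside 386 to 404 CPM (gap 0.889), and tumor-draining replicate 3 held Cryaa at 1.27 beside 2.11 to 2.32 CPM (gap 0.844) and Jchain at 87.9 beside 28.6 to 34.3 CPM (gap 0.839). Tumor-draining replicate 4 held Tapbpl at 106 beside 74.6 to 78.6 CPM (gap 0.854). Healthy replicate 1 held Bcl2a1b at 171 beside 103 to 108 CPM (gap 0.910) and Il27 at 0.977 beside 0.672 to 0.688 CPM (gap 0.937). Healthy replicate 4 held F13a1 at 17.3 beside 10.7 to 11.4 CPM (gap 0.869), Krt7 at 2.44 beside 11.3 to 12.2 CPM (gap 0.950) and Krt8 at 1.23 beside 22.04 to 36.7 CPM (gap 0.849).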

How the results depend on the processing

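The alternatives that use the block in DESeq2 or limma voom, or that leave out all libraries of 1 prefix, were chosen after seeing the data. No called gene changed sign when 1 library was left out, and no called gene given by name changed direction in any alternative run for it. For the counts that changed, the cause was not tested, except that a stricter threshold or a minimum fold reduces calls by construction. Of 47 genes called between tumor-draining and healthy nodes 0 to 44 were kept when 1 library was left out, of 635 between agonist and tumor-draining nodes 316 to 439, and of 1490 between agonist and healthy nodes 820 to 1132. In the data simulated for the first comparison edgeR recovered 36% of genes changed 2-fold without the block and 71% with it, DESeq2 62% and limma voom 33%, with 0, 15, 5 and 0 false calls, so at 4 libraries per group a part of such genes goes uncalled in each fit. The simulated counts followed the fit with the block, so its higher recovery was partly built in.

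In what follows the order is tumor-draining against healthy (47 genes), agonist against tumor-draining (635) and agonist against healthy (1490). The replicate block gave 1495, 3161 and 4781 genes, in DESeq2 2906, 4160 and 5260, and in limma voom 1913, 3282 and 5075. Without the libraries of prefix 1, 2, 3 or 4 the blocked fit gave 107, 193, 164 and 1502 genes, then 1609, 2241, 2311 and 2333, then 2751, 3134, 3172 and 4450. Leaving out 1 library gave 0 to 101, 323 to 477 and 829 to 1243 genes. The limma fits on log2(TPM + 1) gave 1, 271 and 730 genes and on log2(TPM + 0.1) 1, 261 and 727, and counts rebuilt from TPM gave 0, 316 and 933. An adjusted p under 0.01 left 0, 209 and 661 genes. A 2-fold minimum left 43, 311 and 782 genes. DESeq2 gave 370, 1186 and 2154 genes, upper-quartile scaling 30, 973 and 1811, and voom with sample quality weights 21, 957 and 1615. In the first comparison voom gave 1 gene, no filter 75, the 8 libraries alone 25, and leaving out mitochondrial, ribosomal RNA, hemoglobin and antigen receptor genes 24. These settings gave 661, 507, 510 and 501 genes in the second comparison and 1413, 1195, 1328 and 1288 in the third, within 1.5 times the main count. DESeq2 size factors gave 62, 498 and 1324 genes and a CPM filter 42, 911 and 1711, also within it. Upper-quartile scaling moved the median log2 fold change of all genes from -0.02 to -0.11, from 0.02 to 0.02 and from -0.03 to -0.12.

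For the 15, 21 and 24 lists, an estimated correlation left 0, 0 and 3, fry 3, 16 and 20, and the block 21, 19 and 23, and leaving out 1 library gave 16 to 21, 18 to 22 and 23 to 26. For the 5 genes moving back the block gave 290, DESeq2 28, an adjusted p under 0.01 0, each split of the tumor-draining libraries into sets 0 (with 0 to 219 genes called in the first comparison), and leaving out 1 library 0 to 3. Those splits were run without the block here, where the prefix difference favors same-direction over opposite calls. Among genes that the rule takes, printed or not, and the other genes given by name, the block ended 1 call, that of Gbp10 in the second comparison, and added 40, 28 and 14. These counts hold calls that are not printed singly, and apart from them and from the lists given beside the results, the block changed no call among these genes and lists. Upper-quartile scaling ended 12, 1 and 4 calls and added 1, 8 and 5, DESeq2 ended none and added 22, 6 and 4, and limma on log2(TPM + 1) ended 25, 30 and 14 and added 0, 1 and 0. Limma voom ended 26, 3 and 5 calls and added 0, 3 and 0, the 8 libraries alone ended 13, 11 and 5 and added 0, 1 and 0, no filter ended 2, 8 and 10 and added 2, 0 and 0, and DESeq2 size factors ended 0, 9 and 4 and added none. Over all combinations of such a gene and a left-out library, 172, 131 and 96 calls were lost and 5, 4 and 3 gained.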

Other observations

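The gene and list tests given here were set before the data were examined, whereas the genes were chosen after their values were seen: Ccr2, F13a1, Lyz2, Mt1, C1qc, Cd209b, Prg2, Scin, Fos, Atf3, Epcam, Msln, Tff1, Muc1, Krt7, Krt8, Krt18 and Krt19, which lie outside the rule for named genes.

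Genes of monocytes and macrophages went both ways with the agonist, and no difference between those cell types was tested. Ccr2, a chemokine receptor of monocytes and their progeny, fell from 363 ± 64.5 CPM in tumor-draining nodes to 132 ± 11.1 CPM (n = 4 each, log2 fold change -1.46, edgeR adjusted p = 0.000761, lower in 4 of 4 pairs), and F13a1, a transglutaminase of monocytes, from 11.5 ± 2.7 to 4.99 ± 1.43 CPM (log2 fold change -1.20, adjusted p = 0.0170). Lyz2, a lysozyme of myeloid cells, rose from 3161 ± 297 to 5086 ± 865 CPM (log2 fold change 0.69, adjusted p = 0.0450), and C1qc, a complement component of macrophages, from 142 ± 41.3 to 313 ± 72.4 CPM (log2 fold change 1.13, adjusted p = 0.0215). Of 11 monocyte markers 1 rose and 2 fell, over all genes and adjusted over the list alone, and camera did not call the list (adjusted p = 0.0607; 0.480 with an estimated correlation). Mt1, a metallothionein, rose beside its paralog Mt2, from 27.0 ± 5.2 to 91.9 ± 16.3 CPM (log2 fold change 1.77, adjusted p = 0.000650). Within the Cd209 family, whose members are near-identical in parts, Cd209b stood at 50.9 ± 8.2 and 76.8 ± 21.5 CPM (log2 fold change 0.59, adjusted p = 0.133; 0.0178 with the block), opposite in sign to Cd209a (-2.67), Cd209d (-3.01) and Cd209e (-3.45, adjusted p = 0.0892).

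Between tumor-draining and healthy nodes Prg2, a granule protein of eosinophils that some plasma cells also make, rose from 0.287 ± 0.069 to 3.43 ± 1.81 CPM (log2 fold change 3.55, edgeR adjusted p = 0.0181, higher in 4 of 4 pairs), and Scin, an actin-severing protein, from 12.7 ± 2.3 to 40.7 ± 9.6 CPM (log2 fold change 1.68, adjusted p = 0.0105). With the agonist, Prg2 stood at 3.92 ± 2.07 CPM and Scin at 61.6 ± 11.6 CPM. Between agonist and healthy nodes, Fos fell from 306 ± 63.8 to 159 ± 12.2 CPM (log2 fold change -0.95, adjusted p = 0.00248) and Atf3 from 42.35 ± 7.8 to 28.6 ± 2.8 CPM (-0.56, adjusted p = 0.0468), 2 of 18 immediate early genes, with 2 lower and 1 higher adjusted over the list alone and 6 lower and 1 higher with the block, and camera did not call that list (adjusted p = 0.0610). Of 7 Langerhans cell markers, Cd207 fell from 48.1 ± 4.2 to 6.25 ± 4.61 CPM (log2 fold change -2.94, adjusted p = 0.00633) and Epcam from 29.9 ± 6.7 to 15.8 ± 3.1 CPM (log2 fold change -0.92, adjusted p = 0.0107), the same 2 being lower adjusted over the list alone, and camera did not call that list either (adjusted p = 0.123). In the second comparison none of the 7 was called, 1 was lower adjusted over the list alone, and 1 was lower and 1 higher with the block (camera adjusted p = 0.668).

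Camera called none of the remaining lists in any comparison. In the order of the comparisons its adjusted p was 0.0793, 0.716 and 0.0587 for stromal and endothelial markers, 0.949, 0.667 and 0.497 for pancreatic carcinoma and epithelial markers, 0.768, 0.904 and 0.868 for erythroid and platelet markers, and 0.949, 0.419 and 0.374 for mitochondrially encoded genes. The median and mean log2 fold change differed in sign for the type 2 dendritic cell list (-0.01 and 0.15) and the mature dendritic cell list (-0.06 and 0.04) in the first comparison, for Langerhans cell markers (0.13 and -0.13) in the second and for dendritic cell development genes (-0.08 and 0.05) in the third, none of which camera called there. In the second comparison camera placed neutrophil markers lower and erythroid markers higher, against the sign of their medians (0.21 and -0.07), and called neither.

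Epithelial genes varied widely among the libraries, the keratins in healthy nodes as well. Msln, a surface protein of mesothelium and of many pancreatic carcinomas, stood at 3.72, 0.173, 11.2 and 0.0227 CPM in tumor-draining replicates 1 to 4, at 12.1, 1.75, 0.338 and 0 CPM in agonist replicates 1 to 4, and at 0.0244, 0.0560, 0.0191 and 0 CPM in healthy replicates 1 to 4. Tff1, a secreted protein of gastric epithelium, stood at 1.56, 0.0434, 2.10 and 0 CPM, at 2.55, 0.955, 0.528 and 0 CPM, and at 0.0489, 0.0560, 0.0191 and 0 CPM in the same order. Krt8, a keratin of simple epithelia, stood at 29.4, 16.2, 123 and 1.0 CPM, at 149, 17.6, 23.9 and 4.29 CPM, and at 36.7, 22.04, 36.5 and 1.23 CPM in the same order. Like these 3 genes, Krt7, Krt18, Krt19 and the mucin Muc1 were highest in agonist replicate 1 (48.2, 144, 133 and 10.03 CPM) and next highest in tumor-draining replicate 3 (18.7, 92.7, 61.2 and 4.13 CPM), and in healthy nodes Krt18 ranged from 2.57 to 37.9 CPM. None of the 7 was called in any comparison in either fit, Msln, Tff1 and Krt8 having an edgeR adjusted p of 0.407, 0.428 and 0.887 between tumor-draining and healthy nodes.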
